A study of Calotropis procera with 8 samples.

How the data were processed

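Total RNA of leaf, stem, root and whole plant of Calotropis procera was extracted with TRIzol, amplified from an oligo-dT primer, labelled with Cy3 and hybridised to a custom array, per the labels' protocols. The 8 samples fall into 4 groups of 2, with group and replicate taken from the sample labels. Each array was deposited by the authors as scanner output of Agilent Feature Extraction 11.5.1.1, per the file headers, whose processed signal is a background-subtracted and detrended intensity, not scaled between arrays. The deposited mean signal and local background are unprocessed spot intensity values. A deposited table of log2 values of the whole series matched, on each array, log2 of the processed signal minus the array median, with signals under 1 set to 1 on 6 of the arrays, so its scale, centring and direction are known. Its column medians lay between -0.000811 and -1.2e-07. The 2 stem arrays held no signal under 1. No probe was saturated.

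The array holds 170240 probe spots with 122970 distinct sequences, for 44068 transcripts of 22518 loci. Most transcripts have 4 probes, on both strands. The orientation of the assembled transcripts was not given in the sources used here. Isoforms of a locus share sequences, so they are not separate evidence. Names are those of the deposited annotation, which gives a protein name to 11506 transcripts and calls 14712 unknown. No genome was used.

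Log2 processed signal minus each array's 75th percentile was analysed. Because under 50% of probes were well above background on the 2 stem arrays, the percentile was taken over the 53323 probes well above background on all 8 arrays. Control spots were left out, as were 230 probes with an outlier flag on any array, and a probe was tested if it was well above background on both arrays of at least 1 group. The brightest of the 101196 tested probes of a transcript stood for it, which gave 38762 transcripts of 19482 loci, 14017 of them through an antisense probe. Where a probe was well above background on no array of a group, the fold is given as at least the ratio of the bright group's mean to the dim group's mean, with each dim array at the higher of its lowest well-above-background signal and the probe's own.

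One linear model over all 8 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 3.05 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over transcripts, at a threshold of 0.05. The 6 comparisons were each organ against whole plant and each pair of organs. Of 21 gene lists fixed before the data were examined, 20 with at least 5 tested transcripts were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Members were matched by symbol or words of the annotation, and accidental matches were removed by name before expression values were seen. In the fit with an estimated correlation, camera uses only the 4 residual degrees of freedom. At the preset correlation 43 of 120 list tests passed and with an estimated one 0 did. The microbe list, with 3 transcripts, was too short to test.

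Named transcripts were chosen by a rule fixed before the data were examined. For organ against whole plant these were the 6 highest and 6 lowest that passed, changed by at least 1 log2 unit, had one sign on both slides and in every tested probe, and had a protein name, with 1 per name, together with the 2 smallest p-values of up to 8 passing lists. For organ pairs it was the smallest p of each such list, and for organ sets the 5 with the largest smaller difference.

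Replicate 1 of every group lay on slide 1 and replicate 2 on slide 2, so the slide was tested as a block. On 200 simulated differences for leaf versus whole plant among 38762 transcripts, the fit recovered 10% of those of 2 log2 units, 50% of 4, 78% of 6 and 94% of 8, with 4 false calls. With so few changed, the adjusted threshold is stricter than where many transcripts differ, so these rates do not carry over to the comparisons below. No difference was simulated in stem or root. Alternatives fixed before the data were examined were normexp with offset 50, quantile normalization, 2 other filters on dim probes, outlier spots kept, the block, the mean over probes, only the compared groups, another variance prior, the series matrix, a fold threshold and leaving out each replicate. Those chosen after seeing the data were the percentile over all probes, 1 transcript per locus, only probes named specific, a common floor, detection in a compared group, and no stem arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.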

Results

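Expression was measured in leaf, stem, root and whole plant of Calotropis procera, a laticiferous shrub of the dogbane family known for its cardenolides, steroidal compounds that act on the heart. Plants had grown for 3 months in a greenhouse with 16 hours of light and 8 hours of dark. Each of the 4 groups had 2 samples, labelled BR1 and BR2 and called replicates 1 and 2 here. Each sample was hybridised to 1 array of a custom 1-colour design with 170240 probes on assembled transcripts. The labels do not spell out BR or whether the replicates came from separate plants, so the p-values measure only the spread between these samples. The number of arrays limits the precision of every value. Between 36.8% and 58.8% of probes were well above background on an array, and both low values, 36.8% and 49.2%, were from stem. The replicates of a group correlated at r = 0.964 in leaf, 0.929 in stem, 0.965 in root and 0.96 in whole plant over 38762 tested transcripts, which are not independent of each other. Arrays of different groups correlated at 0.767 to 0.904.

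**Figure D1:**
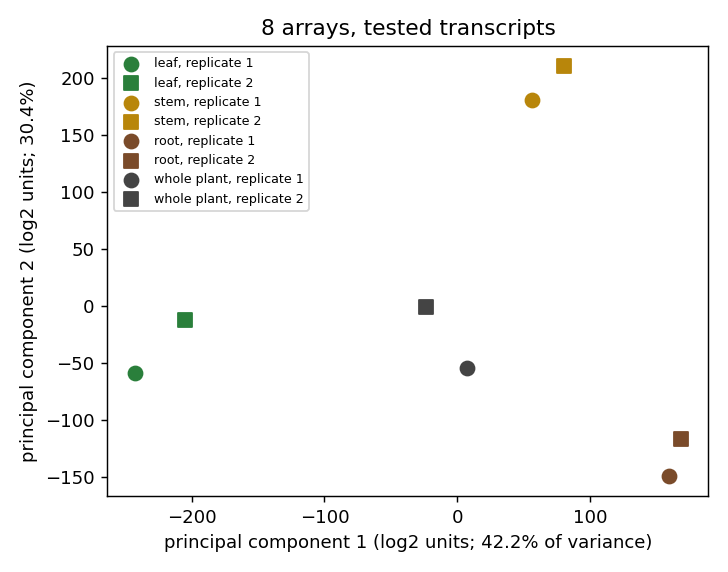
Principal components of the 8 arrays over the tested transcripts, in log2 units, with colour for the group and a circle or square for replicate 1 or 2. Component 1 holds 42.2% of the variance and component 2 holds 30.4%, and leaf, stem and root lie apart with the whole plant arrays between them.

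All levels below are log2 signal minus the array's 75th percentile, differences are between means of 2 arrays (n = 2 per group), and calls are limma adjusted p-values. Both stem arrays were scanned in passes of their own, at a detector voltage of about 470.3 against 429.9 for the other 6 arrays, and their lowest well-above-background signal lay 2.20 log2 units higher. Scan pass and stem cannot be told apart, and this holds for every comparison with stem. Transcripts are ranked by fitted differences, also where only a bound is given, so a bound can lie under the fold of a transcript ranked lower. A bound holds for the brightest probe under the processing described above, and other settings can give smaller differences. Beside a call, "lost in" counts the alternative settings that ended it, of those that still tested the transcript.

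The first question, named in the sample labels, was how each organ differed from the whole plant. Most calls between leaf and whole plant were lower in leaf. A transcript annotated as a bifunctional inhibitor, lipid-transfer or seed storage albumin-like protein was lower in leaf (locus 8, at least 12730-fold, adjusted p = 0.000365). Also lower was KNOPE1, a class I homeobox regulator of meristems (locus 1489, transcript 1, at least 1923-fold, adjusted p = 0.000144). So were polyphenol oxidase, which oxidises phenols (locus 1235, at least 1178-fold, adjusted p = 0.000128) and the root-specific protein RCc3 (locus 13826, at least 1000-fold, adjusted p = 0.000365). A carboxylic ester hydrolase (locus 1718, transcript 2, at least 558-fold, adjusted p = 0.0361, lost in 8 of 20 settings) and a low-molecular-weight cysteine-rich protein (locus 21119, at least 585-fold, adjusted p = 0.000144) completed the 6 lowest. Probes of all 6 were not well above background on either leaf array. The smallest log2 difference in another setting was -9.19 for locus 8, with the mean over probes. For the other 5 it came after normexp. It was -7.36 for KNOPE1, -6.61 for polyphenol oxidase, -6.30 for RCc3, -5.61 for locus 1718 and -5.50 for locus 21119. The highest in leaf was the photosystem II 22 kDa component, which protects the photosystem from excess light (locus 1331, transcript 1, log2 difference 4.80, SE 0.55, adjusted p = 0.00438), at 3.05 ± 0.35 (SD) in leaf and -1.75 ± 0.77 in whole plant. It was followed by a probable xyloglucan endotransglucosylase, a cell wall enzyme (locus 15746, transcript 1, log2 difference 2.96, SE 0.44, adjusted p = 0.0116, lost in 4 of 23 settings and down to log2 0.98 after normexp). Next were a basic secretory protein (locus 14083, log2 difference 2.84, SE 0.52, adjusted p = 0.0256, lost in 5 of 23 settings) and 3-ketoacyl-CoA synthases of locus 7854 (log2 difference 2.66, SE 0.58, adjusted p = 0.0489, but 0.0587 with the slide as a block, lost in 10 of 22 settings and log2 0.89 after normexp) and locus 9315 (log2 difference 2.65, SE 0.39, adjusted p = 0.0117, lost in 5 of 22 settings and down to log2 0.33 after normexp), which elongate fatty acids for wax. The last was a chloroplastic beta-amylase, which degrades starch (locus 7191, transcript 3, log2 difference 2.52, SE 0.54, adjusted p = 0.0447, lost in 10 of 20 settings and down to log2 0.73 after normexp). The synthase of locus 9315 was well above background on 1 whole plant array.

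Of the lists fixed before the data were examined, the photosynthesis list lay higher in leaf than in whole plant (3 higher and 0 lower of 24 transcripts tested, 4 passing when adjusted over the list alone, with median 1.097, adjusted p = 0.000239). Oxygen-evolving enhancer protein 2 was an example (locus 180, transcript 2, log2 difference 2.22, SE 0.41, adjusted p = 0.0263, lost in 7 of 21 settings). The carbon fixation and photorespiration list also lay higher (0 higher and 0 lower of 27 tested, 11 adjusted over the list alone, median 0.34, adjusted p = 0.00601, but median -0.14 with 1 transcript per locus). Its leading members, transcripts 3 and 4 of an aminomethyltransferase of photorespiration (locus 1909), had log2 differences of 1.49 and 1.48 with adjusted p = 0.0696 and 0.0805. The cuticle and wax list lay higher (3 higher and 0 lower of 14 tested, 4 adjusted over the list alone, median 0.84, adjusted p = 0.0237). Among the lists lower in leaf, class III peroxidases stood first (0 higher and 8 lower of 11 tested, 9 adjusted over the list alone, median -6.57, adjusted p = 3.06e-11). Transcripts 6 and 5 of class III peroxidase 3 (locus 1260) had log2 differences of -6.88 and -6.93, each with adjusted p = 0.000587. The xylem and secondary wall list was lower (0 higher and 17 lower of 41 tested, 20 adjusted over the list alone, median -1.28 but -0.47 after normexp and -0.49 with a common floor, adjusted p = 7.53e-07). Cellulose synthase subunit 8 of secondary walls was its example (locus 195, transcript 3, log2 difference -7.29, SE 0.66, adjusted p = 0.00193). Aquaporins, the water channels, were lower as a list (0 higher and 1 lower of 8 tested, 6 adjusted over the list alone, median -5.63, adjusted p = 0.000533). A TIP-type aquaporin of the vacuole membrane, at 4.21 and 0.04 on the 2 whole plant arrays, was lower (locus 13505, at least 667-fold, adjusted p = 0.00649, lost in 1 of 22 settings). The aquaporin of locus 836 had a log2 difference of -6.11 with adjusted p = 0.0567, or 0.0108 with the slide as a block. The root uptake list was lower (0 higher and 5 lower of 45 tested, 11 adjusted over the list alone, median -0.45, adjusted p = 0.00345). Its members included the high-affinity nitrate transporter of locus 16529 (at least 569-fold, adjusted p = 0.000428) and the phosphate transporter of locus 16612 (at least 1077-fold, adjusted p = 0.000639, lost in 1 of 23 settings and down to log2 -2.02 with probes well above background on all 8 arrays). The log2 -2.02 of locus 16612 came from another of its probes, with adjusted p = 0.0787. The sterol and cardenolide list was lower (0 higher and 7 lower of 34 tested, 7 adjusted over the list alone, median -0.42, adjusted p = 0.00345). Squalene epoxidase, which makes the epoxide from which plant sterols are built, was lower in leaf (locus 811, transcript 9, at least 33.2-fold, adjusted p = 0.00438, lost in 2 of 20 settings, with log2 -2.80 with a common floor and -1.86 after normexp). Regulators of shoot and leaf identity were lower (0 higher and 3 lower of 7 tested, 4 adjusted over the list alone, median -1.55, adjusted p = 0.00601, but median 0.16 with only specific probes). They were led by the homeobox protein knotted-1-like of locus 6300 (at least 148-fold, adjusted p = 0.000639), a meristem regulator whose family is kept off in most leaves.

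With an estimated correlation these list calls were lost. The adjusted p was 0.159 for photosynthesis, 0.187 for carbon fixation, 0.361 for cuticle, 0.113 for peroxidases, xylem and root uptake alike, 0.187 for aquaporins, 0.206 for sterols and 0.159 for the identity regulators, all with an estimated correlation. Some calls also ended with 1 transcript per locus, a setting chosen after seeing the data, where the adjusted p was 0.581 for carbon fixation with median -0.14, 0.0522 for cuticle with median 0.55, 0.171 for root uptake with median -0.34, 0.213 for sterols with median -0.37 and 0.203 for identity regulators with median -0.70. Only specific probes, also chosen afterwards, gave an adjusted p of 0.142 for photosynthesis with median 0.75, 0.296 for carbon fixation with median 0.34, 0.142 for cuticle with median 0.55, 0.142 for root uptake with median -0.22, 0.346 for sterols with median -0.20 and 0.599 for identity regulators with median 0.16. Cuticle had an adjusted p of 0.0638 with probes well above background on all 8 arrays, 0.065 without leaf replicate 2 and 0.0508 without whole plant replicate 2. Root uptake had an adjusted p of 0.0809 with probes well above background on all 8 arrays and 0.065 without leaf replicate 2. Sterols had an adjusted p of 0.0638 with probes well above background on all 8 arrays. Identity regulators had an adjusted p of 0.0645 with the mean over probes and 0.0667 with only the groups compared. With the slide, which equals the replicate number, as a block, the cuticle list had adjusted p = 0.0503. The other 11 lists did not pass, with adjusted p from 0.106 for the cell cycle to 0.849 for heat and water stress. Among these, chlorophyll and carotenoids passed in 5 of 23 alternative settings, root barrier in 4, the cell cycle in 2 and the ribosome in 1. In all, 2068 of 38762 transcripts differed, 280 higher and 1788 lower in leaf, from 1588 loci (2440 with the slide as a block). The differences on the 2 slides correlated at r = 0.73 across all tested transcripts. Of the 1912 calls with several probes, 92.1% had all probes of one sign. The count fell to 558 without whole plant replicate 1, and normexp background correction gave 1309 higher and 2260 lower. The 75th percentile over all probes gave 569 higher and 1623 lower.

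Stem differed from whole plant in both directions. The highest named transcript was an AP2 domain CBF protein, of a family of cold-responsive transcription factors (locus 2854, log2 difference 7.39, SE 1.94, adjusted p = 0.0491, lost in 9 of 22 settings). The other 5 were a non-specific lipid-transfer protein (locus 12135, log2 difference 5.28, SE 1.27, adjusted p = 0.0407, lost in 6 of 22 settings) and a rhomboid-like protease (locus 6084, transcript 5, at least 6.61-fold, adjusted p = 0.0145, lost in 3 of 19 settings and down to log2 0.80 with a common floor). Among them too were a phosphate starvation response protein (locus 1769, transcript 2, at least 11.7-fold, adjusted p = 0.0131, lost in 1 of 21 settings and down to log2 1.63 with a common floor), a kinase (locus 1605, transcript 2, log2 difference 4.33, SE 0.87, adjusted p = 0.0273, lost in 4 of 21 settings) and molybdopterin synthase sulphurylase (locus 1238, transcript 6, log2 difference 4.31, SE 0.76, adjusted p = 0.0213, lost in 3 of 21 settings). The lowest were a class III peroxidase of locus 9882 (at least 183-fold, adjusted p = 0.000824), the cysteine-rich protein of locus 21119 (at least 124-fold, adjusted p = 0.000824) and the TIP-type aquaporin of locus 13505 (at least 141-fold, adjusted p = 0.017, lost in 4 of 21 settings). With them were the nitrate transporter of locus 16529 (at least 120-fold, adjusted p = 0.00188), the phosphate transporter of locus 16612 (log2 difference -8.29, SE 0.67, adjusted p = 0.00395, lost in 1 of 22 settings and down to log2 -0.15 with probes well above background on all 8 arrays) and a putative cellulose synthase (locus 6181, transcript 3, log2 difference -8.002, SE 0.46, adjusted p = 0.00149). These last 2 were well above background on 1 of the 2 stem arrays, and the kinase on 1 whole plant array. The log2 -0.15 of locus 16612 came from another of its probes, with adjusted p = 0.851, so its probes disagreed on the size.

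The cytosolic ribosome list lay higher in stem (9 higher and 1 lower of 96 tested, 8 adjusted over the list alone, median 0.74, adjusted p = 0.00124, but median -0.30 from the series matrix). Its leading members went both ways, with a small subunit protein of locus 17700 higher (log2 difference 2.15, SE 0.39, adjusted p = 0.0221, lost in 5 of 21 settings) and a large subunit protein of locus 9555 lower (at least 1.91-fold, adjusted p = 0.0247, lost in 7 of 20 settings, but log2 difference 0.57 after normexp). Sterol and cardenolide synthesis also lay higher (7 higher and 0 lower of 34 tested, 10 adjusted over the list alone, median 1.105 but 0.07 from the series matrix, adjusted p = 0.00748). The reductase of locus 1054, 3-hydroxy-3-methylglutaryl coenzyme A reductase, the rate-limiting enzyme of the mevalonate pathway, was higher (log2 difference 2.66, SE 0.49, adjusted p = 0.0228, lost in 5 of 21 settings). Squalene synthase, which commits that pathway to sterols, was higher too (locus 12515, transcript 4, log2 difference 1.94, SE 0.41, adjusted p = 0.0312, lost in 7 of 20 settings). Lower lists included xylem and secondary wall (0 higher and 8 lower of 41 tested, 12 adjusted over the list alone, median -0.75, adjusted p = 0.00161). Its leading member was cinnamoyl-CoA reductase of lignin synthesis (locus 1305, transcript 3, at least 12.3-fold, adjusted p = 0.00334). Root barrier genes were lower (0 higher and 10 lower of 28 tested, 13 adjusted over the list alone, median -1.38 but -0.22 after normexp, adjusted p = 0.00205). Among them were CASP-like membrane proteins of locus 16212 (at least 19.3-fold, adjusted p = 0.007, lost in 1 of 21 settings) and locus 22054 (log2 difference -3.23, SE 0.55, adjusted p = 0.0203, lost in 3 of 21 settings). Latex and defence proteins were lower (2 higher and 10 lower of 39 tested, 17 adjusted over the list alone, median -0.54 but 0.49 after normexp and 0.44 with probes well above background on all 8 arrays, adjusted p = 0.00391). Polyphenol oxidase (locus 1235, at least 249-fold, adjusted p = 0.000508) and a major latex-like protein (locus 21543, at least 80.7-fold, adjusted p = 0.00132) were lower, although 1 of 4 probes of the former and 2 of 4 of the latter had the other sign. Aquaporins were lower (0 higher and 2 lower of 8 tested, 3 adjusted over the list alone, median -3.48, adjusted p = 0.00748). Root uptake was lower (2 higher and 6 lower of 45 tested, 11 adjusted over the list alone, median -0.25 but 0.20 after normexp and 0.04 without whole plant replicate 1, adjusted p = 0.0398). Carbon fixation was lower too (0 higher and 1 lower of 27 tested, 0 adjusted over the list alone, median -0.60 but 0.07 after normexp and 0.28 with only specific probes, adjusted p = 0.00748). In these, the aquaporin of locus 11121 (at least 1.53-fold, adjusted p = 0.0183, lost in 7 of 20 settings, but log2 difference 0.62 after normexp) and transcript 2 of the Rubisco small chain (locus 619, transcript 2, log2 difference -3.50, SE 0.82, adjusted p = 0.0385, lost in 6 of 20 settings) were lower. A glyoxylate reductase of locus 1508 was not well above background in either group.

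With an estimated correlation the adjusted p was 0.528 for the ribosome list, 0.296 for xylem, latex and root uptake alike, 0.382 for root barrier, aquaporins and sterols alike, and 0.306 for carbon fixation, so no list call held. Calls that ended with 1 transcript per locus had an adjusted p of 0.315 for carbon fixation with median -0.48 and 0.372 for sterols with median 0.78. Those that ended with only specific probes had an adjusted p of 0.767 for carbon fixation with median 0.28, 0.152 for xylem with median -0.37, 0.418 for root barrier with median -0.04, 0.128 for aquaporins with median -1.28 and 0.507 for sterols with median 1.08. Sterols had an adjusted p of 0.088 with normexp. The ribosome had an adjusted p of 0.0869 with normexp and 0.0635 with the series matrix. Root uptake had an adjusted p of 0.159 with quantile normalization, 0.247 with probes well above background on all 8 arrays, 0.0835 with the series matrix, 0.151 without whole plant replicate 1, 0.0778 without stem replicate 2, 0.0839 with the percentile over all probes and 0.0931 with a common floor. Latex proteins had an adjusted p of 0.712 with probes well above background on all 8 arrays. Carbon fixation had an adjusted p of 0.0559 with the mean over probes. Aquaporins had an adjusted p of 0.0778 without stem replicate 2 and 0.0931 with a common floor. The other 12 lists did not pass, with adjusted p from 0.0874 for cuticle and for phloem to 0.738 for the identity regulators of the shoot. Of these, jasmonate and wounding (median 1.60) passed in 7 of 22 alternative settings and phloem (median -0.17) in 6. Photosynthesis and peroxidases each passed in 3, cuticle in 2 and root identity regulators in 1. In all, 5317 transcripts from 3636 loci differed, 2737 higher and 2580 lower in stem. The count was far lower with only the groups compared, as given under processing below. With the slide as a block there were 8763, and the differences on the 2 slides correlated at r = 0.612 across transcripts. Of 4685 calls with several probes only 70.9% had all probes of one sign. Among the calls higher in stem, 173 were well above background on no array of either group, against 0 of those lower. The split depended on the processing, with 480 higher and 6928 lower from the median-centred series matrix, 1502 and 4125 with the percentile over all probes, 2219 and 4751 after quantile normalization and 20646 and 3021 after normexp background correction. The median over all transcripts moved with it, from 0.26 to 0.79 after normexp and -0.78 in the series matrix, and a list test is relative to that shift. Without whole plant replicate 1 the count was 159.

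Among the 6 lowest in root against whole plant were a chlorophyll a/b-binding protein, which harvests light (locus 12086, log2 difference -10.34, SE 0.73, adjusted p = 0.000639), at -3.88 ± 1.48 (SD) in root and 6.46 ± 0.92 in whole plant. The others included the small chain of the carbon-fixing enzyme Rubisco (locus 619, transcript 5, log2 difference -10.06, SE 0.47, adjusted p = 0.000194) and a chloroplastic carotenoid cleavage dioxygenase (locus 66, transcript 1, log2 difference -10.84, SE 0.55, adjusted p = 0.000244). Glucose-1-phosphate adenylyltransferase of starch synthesis (locus 5275, at least 361-fold, adjusted p = 0.000194), catalase (locus 12281, at least 981-fold, adjusted p = 0.000194, lost in 1 of 23 settings and down to log2 -0.50 with probes well above background on all 8 arrays) and a lipid-transfer protein (locus 12053, transcript 3, at least 174-fold, adjusted p = 0.000194) completed them. The log2 -0.50 of catalase came from its other probe, with adjusted p = 0.44. The highest were a Myb-related protein (locus 14091, at least 238-fold, adjusted p = 0.000194), an SKP1-interacting protein (locus 15483, at least 202-fold, adjusted p = 0.0181, lost in 4 of 22 settings) and ascorbate oxidase, an apoplastic enzyme (locus 14879, at least 63-fold, adjusted p = 0.00104). Next came BAP1 (locus 13083, log2 difference 6.95, SE 1.15, adjusted p = 0.0162, lost in 5 of 23 settings), linalool synthase, which makes a volatile terpene (locus 10914, log2 difference 6.93, SE 1.42, adjusted p = 0.033, lost in 6 of 23 settings), and a desiccation-related protein (locus 18089, log2 difference 6.78, SE 1.20, adjusted p = 0.0203, lost in 3 of 22 settings), detected on 1 of 2 whole plant arrays.

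The photosynthesis list was lower in root (0 higher and 12 lower of 24 tested, 16 adjusted over the list alone, median -2.37, adjusted p = 2.79e-09). Transcripts 2 and 1 of oxygen-evolving enhancer protein 2 (locus 180) had log2 differences of -7.37 and -7.28. Chlorophyll and carotenoid synthesis was lower (0 higher and 12 lower of 26 tested, 15 adjusted over the list alone, median -1.68, adjusted p = 3.51e-08, but median -0.33 and adjusted p = 0.749 with 1 transcript per locus and median -0.16 with a common floor). Its phytoene synthase, the entry enzyme of carotenoid synthesis (locus 4400, transcript 2, at least 4.11-fold, adjusted p = 0.00104, lost in 2 of 20 settings and down to log2 0.00 with a common floor), and zeaxanthin epoxidase (locus 4525, transcript 1, at least 2.25-fold, adjusted p = 0.0029, lost in 3 of 20 settings, but log2 difference 0.88 with no filter on dim probes) were dim on all arrays of root. Carbon fixation (1 higher and 6 lower of 27 tested, 15 adjusted over the list alone, median -0.92, adjusted p = 0.000281) was lower. So was xylem and secondary wall (0 higher and 8 lower of 41 tested, 11 adjusted over the list alone, median -0.44, adjusted p = 0.00902), with cinnamoyl-CoA reductases of locus 4365 (log2 difference -3.92, SE 0.33, adjusted p = 0.00122) and locus 1305 (log2 difference -3.70, SE 0.44, adjusted p = 0.00475, lost in 1 of 20 settings). In the other direction, the jasmonate and wounding list was higher in root (5 higher and 0 lower of 16 tested, 9 adjusted over the list alone, median 1.97 but 0.61 after normexp, adjusted p = 1.23e-05). Jasmonate ZIM domain 2, a repressor that jasmonate induces, was higher (locus 11408, transcript 4, log2 difference 5.32, SE 0.67, adjusted p = 0.00581). The same held for 12-oxophytodienoate reductase 7 of jasmonate synthesis (locus 12837, transcript 1, log2 difference 5.71, SE 0.72, adjusted p = 0.00595, lost in 1 of 21 settings). Class III peroxidases (1 higher and 0 lower of 11 tested, 2 adjusted over the list alone, median 0.37, adjusted p = 0.018) lay higher as a list. Latex and defence proteins (6 higher and 3 lower of 39 tested, 12 adjusted over the list alone, median 0.36, adjusted p = 0.0388) and cytosolic ribosome (0 higher and 0 lower of 96 tested, 0 adjusted over the list alone, median 0.37, adjusted p = 0.00327) did so too. Their leading members were the peroxidase of locus 9546 (log2 difference 3.45, SE 0.50, adjusted p = 0.00969, lost in 3 of 22 settings), polyphenol oxidase (locus 1235, log2 difference 2.78, SE 0.35, adjusted p = 0.00595) and a major latex-like protein (locus 21543, log2 difference 3.34, SE 0.46, adjusted p = 0.00793, lost in 3 of 22 settings). The peroxidase of locus 8782 had a log2 difference of 1.66 with adjusted p = 0.0659, and the small subunit ribosomal proteins of loci 2124 and 1066 had -1.43 and 1.64 with adjusted p = 0.0593 and 0.0989.

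With an estimated correlation the adjusted p was 0.191 for photosynthesis, 0.259 for carbon fixation, 0.281 for chlorophyll and xylem alike, 0.338 for jasmonate and latex alike, 0.408 for peroxidases and 0.646 for the ribosome, so no list call held. Taking 1 transcript per locus gave an adjusted p of 0.749 for chlorophyll and carotenoids with median -0.33 and 0.781 for xylem with median -0.44. Taking only specific probes gave an adjusted p of 0.997 for carbon fixation with median -0.20 and 0.891 for xylem with median -0.31. Peroxidases had an adjusted p of 0.0505 with quantile normalization, 0.0572 without root replicate 1 and 0.168 without whole plant replicate 2. Latex proteins had an adjusted p of 0.0505 with quantile normalization, 0.0529 with no filter on dim probes, 0.0519 with the series matrix, 0.0518 without stem replicate 1, 0.157 without root replicate 2, 0.0518 without stem replicate 2, 0.082 without whole plant replicate 2 and 0.0518 without the stem arrays. The ribosome had an adjusted p of 0.119 without root replicate 1 and 0.0645 without whole plant replicate 2. Xylem had an adjusted p of 0.0981 without whole plant replicate 1. The other 12 lists did not pass, with adjusted p from 0.0618 for aquaporins to 0.854 for the cell cycle. Among these, aquaporins passed in 4 of 21 alternative settings, sterols in 4 of 23 and phloem in 3 of 23. In all, 2649 transcripts from 1732 loci differed, 794 higher and 1855 lower in root (3147 with the slide as a block). Between slides the differences correlated at r = 0.751 across transcripts. The count was 760 without whole plant replicate 2 and 845 without root replicate 2.

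**Figure D2:**
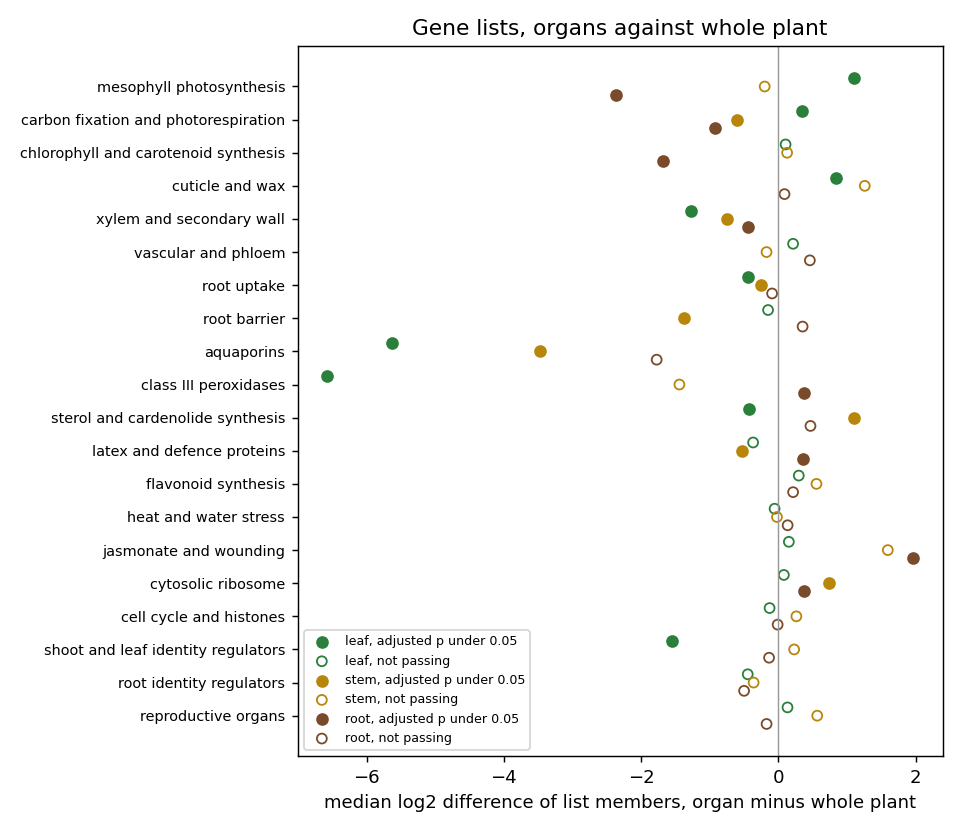
Median log2 difference of the tested members of each of the 20 lists, organ minus whole plant, with colour for the organ and filled points for lists with camera adjusted p under 0.05 at the preset correlation. The photosynthesis list lies at 1.097 in leaf and -2.37 in root, and the class III peroxidases at -6.57 in leaf and 0.37 in root.

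In leaf against root, the Rubisco small chain was higher in leaf (locus 619, transcript 5, log2 difference 10.25, SE 0.47, adjusted p = 6.27e-05), at 7.68 ± 0.11 (SD) against -2.57 ± 0.29 in root. Oxygen-evolving enhancer protein 2 was higher as well (locus 180, transcript 2, log2 difference 9.59, SE 0.41, adjusted p = 5.67e-05). The photosynthesis list (14 higher and 0 lower of 24 tested, 16 adjusted over the list alone, median 3.28 but 1.19 after normexp, adjusted p = 2.23e-09) lay higher in leaf. The chlorophyll and carotenoid list (17 higher and 1 lower of 26 tested, 18 adjusted over the list alone, median 2.88, adjusted p = 7.35e-07, but median 0.22 and adjusted p = 0.312 with 1 transcript per locus and median 0 with a common floor) and its phytoene dehydrogenase (locus 3894, transcript 3, log2 difference 5.56, SE 0.41, adjusted p = 0.000244) were higher too, and so was the carbon fixation list (12 higher and 1 lower of 27 tested, 15 adjusted over the list alone, median 0.75, adjusted p = 5.48e-05). Class III peroxidases were lower in leaf (0 higher and 9 lower of 11 tested, 10 adjusted over the list alone, median -7.09, adjusted p = 7.23e-09). An example was the peroxidase of locus 9546 (at least 298-fold, adjusted p = 7.79e-05). Sterol and cardenolide synthesis was lower in leaf (0 higher and 10 lower of 34 tested, 12 adjusted over the list alone, median -0.9998, adjusted p = 0.000171). Its leading member was squalene epoxidase (locus 811, transcript 9, at least 28.6-fold, adjusted p = 0.0015, lost in 1 of 20 settings, with log2 -2.59 with a common floor and -1.60 after normexp). The jasmonate list was lower in leaf (0 higher and 8 lower of 16 tested, 10 adjusted over the list alone, median -2.91, adjusted p = 0.000747). It included a TIFY protein of the family of jasmonate repressors (locus 8830, transcript 3, at least 904-fold, adjusted p = 0.000301). Root barrier genes were lower in leaf (0 higher and 8 lower of 28 tested, 11 adjusted over the list alone, median -0.50 but -0.10 after normexp, adjusted p = 0.033). It included a CASP-like protein (locus 16212, at least 256-fold, adjusted p = 0.000246). The xylem list was lower in leaf (6 higher and 14 lower of 41 tested, 26 adjusted over the list alone, median -0.96, adjusted p = 0.0401). Its leading member, cinnamoyl-CoA reductase, went the other way (locus 4365, transcript 2, log2 difference 4.91, SE 0.33, adjusted p = 0.000201), with 1 of its 3 probes of the opposite sign.

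With an estimated correlation the adjusted p was 0.13 for photosynthesis, carbon fixation and peroxidases alike, 0.227 for sterols, 0.265 for chlorophyll, 0.284 for xylem, 0.324 for jasmonate and 0.432 for root barrier, so no list call held. At 1 transcript per locus the adjusted p was 0.312 for chlorophyll and carotenoids with median 0.22 and 0.153 for jasmonate with median -1.72. At specific probes alone the adjusted p was 0.556 for carbon fixation with median 0.03, 0.187 for chlorophyll and carotenoids with median 2.46, 0.0894 for sterols with median -0.93 and 0.0894 for jasmonate with median -2.77. Root barrier had an adjusted p of 0.061 with normexp, 0.596 with probes well above background on all 8 arrays, 0.0744 without root replicate 2 and 0.189 with a common floor. Xylem had an adjusted p of 0.0638 with no filter on dim probes, 0.0864 with probes well above background on all 8 arrays, 0.0557 with only the groups compared, 0.0749 without whole plant replicate 1, 0.0971 without leaf replicate 2, 0.0749 without whole plant replicate 2 and 0.114 with a common floor. The other 12 lists did not pass, with adjusted p from 0.0687 for latex and defence proteins to 0.861 for phloem. Among these, latex and defence proteins passed in 7 of 23 alternative settings, root uptake in 3 of 23 and aquaporins in 1 of 21. In all, 8397 transcripts from 5289 loci differed, 3996 higher and 4401 lower in leaf, against 9360 with the slide as a block. The differences on the 2 slides correlated at r = 0.878 across transcripts. The count was 4820 without leaf replicate 1 and 4792 without root replicate 2.

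In leaf against stem, oxygen-evolving enhancer protein 2 was higher in leaf (locus 180, transcript 2, log2 difference 4.48, SE 0.41, adjusted p = 0.00128), with 2 of 3 probes of that sign, and so was transcript 2 of the Rubisco small chain (locus 619, transcript 2, log2 difference 6.04, SE 0.82, adjusted p = 0.00328). The photosynthesis list (11 higher and 0 lower of 24 tested, 12 adjusted over the list alone, median 1.26 but 0.07 after normexp, adjusted p = 0.00137) lay higher in leaf. So did the carbon fixation list (10 higher and 1 lower of 27 tested, 11 adjusted over the list alone, median 0.94 but 0.17 after normexp, adjusted p = 0.00118). Sterol and cardenolide synthesis lay lower in leaf than in stem (1 higher and 17 lower of 34 tested, 21 adjusted over the list alone, median -1.50 but -0.25 from the series matrix, adjusted p = 0.00118). Squalene epoxidase was its leading member (locus 811, transcript 9, at least 241-fold, adjusted p = 0.000856), with all 4 probes of one sign. With an estimated correlation the adjusted p of each of these 3 lists was 0.362. Reduced to 1 transcript per locus, the adjusted p was 0.373 for carbon fixation with median 0.26 and 0.304 for sterols with median -1.49. Reduced to specific probes, the adjusted p was 0.48 for photosynthesis with median 0.43, 0.487 for carbon fixation with median 0.85 and 0.487 for sterols with median -1.23. The other 17 lists did not pass, with adjusted p from 0.107 for peroxidases to 0.94 for flavonoid synthesis. In all, 14456 transcripts from 8704 loci differed, 5600 higher and 8856 lower in leaf (16718 with the slide as a block). The count was lower with only the groups compared and in each fit with 1 array left out, as given under processing below. Slide by slide the differences correlated at r = 0.793 across transcripts. Of those lower in leaf, 567 were well above background on no array of either group. The split was 12004 higher and 2645 lower in the median-centred series matrix, 9382 and 4822 with the percentile over all probes, 8541 and 5773 after quantile normalization and 4634 and 23290 after normexp, so which direction held more calls differed between these settings.

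In stem against root, a photosystem I subunit of locus 12074 was higher in stem (at least 25.4-fold, adjusted p = 0.000411). The photosynthesis list (15 higher and 2 lower of 24 tested, 18 adjusted over the list alone, median 2.54, adjusted p = 0.00152) lay higher, as did the chlorophyll and carotenoid list (14 higher and 0 lower of 26 tested, 18 adjusted over the list alone, median 1.91, adjusted p = 0.00167). Phytoene synthase, the leading member of the latter, was not well above background in either organ, and with a common floor for dim signals the list had median 0 and adjusted p = 0.423. The root barrier list was lower in stem (1 higher and 12 lower of 28 tested, 16 adjusted over the list alone, median -1.34 but -0.46 after normexp, adjusted p = 0.000206). An example was a CASP-like protein (locus 16212, at least 54-fold, adjusted p = 0.00124). Latex and defence proteins were lower (3 higher and 13 lower of 39 tested, 17 adjusted over the list alone, median -0.74 but 0.38 after normexp, adjusted p = 0.00379). Their leading member was polyphenol oxidase (locus 1235, at least 1706-fold, adjusted p = 9.43e-05). Class III peroxidases were lower (3 higher and 6 lower of 11 tested, 10 adjusted over the list alone, median -2.36 but 0.70 after normexp, adjusted p = 0.0101), with the peroxidase of locus 9882 (at least 233-fold, adjusted p = 0.0002). The jasmonate list was lower (0 higher and 6 lower of 16 tested, 6 adjusted over the list alone, median -1.16, adjusted p = 0.0101), with 12-oxophytodienoate reductase 7 (locus 12837, transcript 1, log2 difference -3.64, SE 0.72, adjusted p = 0.0138, lost in 2 of 20 settings). That reductase was at -5.356 on stem replicate 1, under that array's lowest well-above-background signal of -5.005. The vascular and phloem list was lower (0 higher and 6 lower of 23 tested, 6 adjusted over the list alone, median -0.85 but 0.21 after normexp, adjusted p = 0.00976), with the sugar transporter SWEET2 (locus 12676, transcript 2, at least 1.97-fold, adjusted p = 0.00899, lost in 3 of 19 settings, but log2 difference 1.35 after normexp). With an estimated correlation the adjusted p was 0.448 for the first 4 lists named here, peroxidases and phloem, and 0.461 for jasmonate with an estimated correlation. For 1 transcript per locus the adjusted p was 0.548 for chlorophyll and carotenoids with median 1.12, 0.548 for phloem with median -0.59 and 0.135 for jasmonate with median -1.15. For specific probes alone the adjusted p was 0.582 for chlorophyll and carotenoids with median 0.72, 0.488 for phloem with median -0.94, 0.0567 for root barrier with median -0.72 and 0.149 for jasmonate with median -1.16. Chlorophyll and carotenoids had an adjusted p of 0.0655 with normexp, 0.305 with probes well above background on all 8 arrays and 0.423 with a common floor. Peroxidases had an adjusted p of 0.212 with quantile normalization. Phloem had an adjusted p of 0.0969 with probes well above background on all 8 arrays. Latex proteins had an adjusted p of 0.2 with probes well above background on all 8 arrays. Jasmonate had an adjusted p of 0.0604 without stem replicate 1. The other 13 lists did not pass, with adjusted p from 0.0722 for cuticle to 0.977 for flavonoid synthesis. In all, 10923 transcripts from 7007 loci differed, 6705 higher and 4218 lower in stem (13762 with the slide as a block). The slides' differences correlated at r = 0.784 across transcripts. Among the calls higher in stem, 299 were well above background on no array of either group, against 0 of those lower. The split was 1631 and 9354 in the series matrix, 4088 and 6698 with the percentile over all probes, 4835 and 6829 after quantile normalization and 22794 and 3831 after normexp. Without root replicate 1 the count was 2953.

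Transcripts higher in 1 organ than in both others were collected for leaf, stem and root. Every set was smaller in each fit with 1 array left out, with the ranges given under processing below. In leaf these transcripts numbered 2282, from 1287 loci. The 5 with the largest margin were a germin-like protein (locus 3067, at least 310-fold over stem, adjusted p = 0.0039) and catalase, which removes hydrogen peroxide. The others were CYP71AU1, a cytochrome of specialised metabolism, a major latex-like protein and YABBY1, a regulator of leaf polarity. Catalase was at least 2195-fold higher than in root, but its other probe, the one well above background on all 8 arrays, gave a log2 difference of 0.995 with adjusted p = 0.0759. For the other 4, in that order, the log2 differences against root were 11.04 (SE 1.48), 7.77 (SE 0.49), 9.47 (SE 1.13) and 7.69 (SE 1.68), and all but CYP71AU1 were well above background on only 1 root array. The call of YABBY1 was lost in 2 of 22 settings against root and in 4 of 21 against stem. Against stem catalase had a log2 difference of 8.54 (SE 0.42), with its 2 probes of opposite sign, but -0.78 with probes well above background on all 8 arrays. In root they numbered 1432, from 1128 loci, led by polyphenol oxidase, at least 8080-fold over leaf and at least 1706-fold over stem. With the mean over its probes, leaf minus root was log2 -8.81 and stem minus root -6.61. Next came a major latex-like protein of locus 21543, at least 3871-fold over leaf, the root-specific protein RCc3, at least 5332-fold over leaf, a family 1 glycosyl hydrolase of locus 12434, at least 1092-fold over leaf, and an oxidoreductase of locus 13853, at least 966-fold over leaf.

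In stem they numbered 3873, from 2634 loci, and 3648 of these were well above background on both stem arrays. The 5 with the largest margin were the knotted-1-like homeobox protein of locus 6300 (log2 difference 5.99, SE 0.51, adjusted p = 0.00119), given against root, and 2 transcripts of locus 290 annotated as melibiase and as a family 27 glycosyl hydrolase, enzymes that release galactose. The others were a protein of the spindle-binding Xklp2-targeting family (locus 2924, transcript 2, log2 difference 5.21, SE 0.58, adjusted p = 0.00269), and the lipid-transfer protein of locus 12135 (log2 difference 7.42, SE 1.27, adjusted p = 0.00935). The transcript of locus 2924 was at -8.42 on root replicate 1, under that array's lowest well-above-background signal of -7.63. Against leaf, the call of the lipid-transfer protein was lost in 4 of 22 settings. The 2 transcripts of locus 290 had log2 differences of 5.43 (SE 0.72) and 5.28 (SE 0.61) over root. Each set rests on 2 comparisons that share the organ's own arrays. In 20 simulations with no change in any transcript, none met the rule. Those simulations do not estimate false members of sets drawn where many transcripts differ. Independent calls would have given 577 for leaf, 1532 for stem and 479 for root. With the slide as a block the sets numbered 2460, 5545 and 1707 in leaf, stem and root. The stem set fell to 647 with the series matrix values and to 739 without root replicate 1, and rose to 18962 after normexp.

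**Figure D3:**
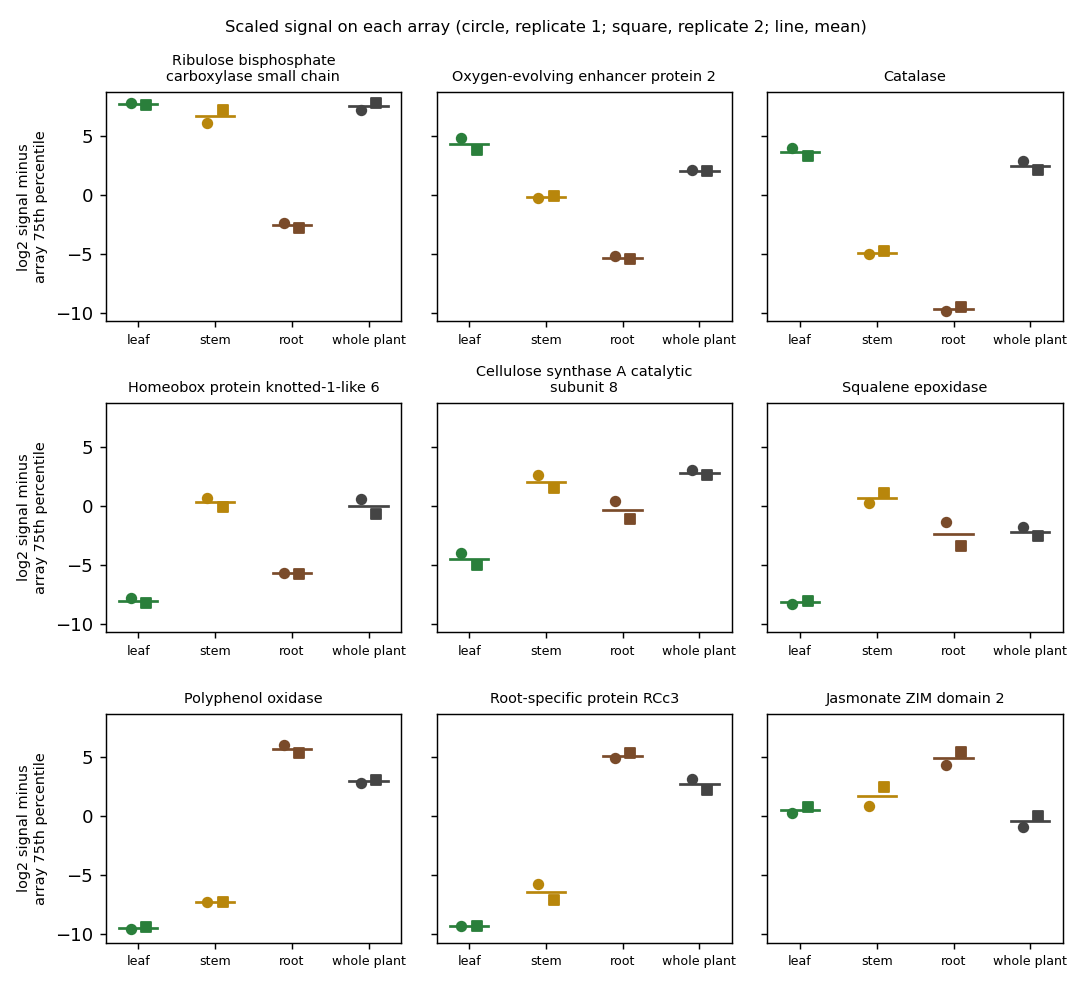
Scaled log2 signal of 9 named transcripts on each of the 8 arrays, with circles for replicate 1, squares for replicate 2 and lines for the mean of 2. The Rubisco small chain lies at 7.68 ± 0.11 (SD) in leaf and -2.57 ± 0.29 in root, and polyphenol oxidase at 5.72 ± 0.46 in root and -7.27 ± 0.01 in stem, where it was not well above background.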

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

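Arrays with 2 samples per group and signals near background limit these counts. Of 263 comparisons of a count with its reported value, 195 stayed within 1.5 times. Of 2664 comparisons for named transcripts, 2458 kept direction and side of the threshold, 176 no longer passed, 23 newly passed, 5 reversed and 2 that passed in neither fit changed direction. Of 2670 for list tests, 2392 kept both, 95 no longer passed, 78 newly passed and 105 that passed in neither fit changed the direction of the test. Of the passing lists, the median lay on the other side of 0 in 12 comparisons for 9 list tests, and 6 of these, all after normexp, still passed with the direction of the test, relative to other transcripts, kept. The percentile over all probes, 1 transcript per locus, only specific probes, the common floor, detection in a compared group and the fit without stem arrays were chosen after seeing the data. The cause of the moves below was not tested, except where fewer transcripts or samples entered.

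After normexp the counts were 3569 for leaf, 23667 for stem and 4001 for root against whole plant, 27924 for leaf versus stem, 26625 for stem versus root and 18962 for the stem set. With probes well above background on all 8 arrays, which left 26534 transcripts, they were 1224 for leaf versus whole plant and 901 for the root set, and 40 of the 47 named comparisons still tested passed, in place of 119 of 126. With only the compared groups, stem versus whole plant gave 541, leaf versus stem 9134, stem versus root 6824 and the stem set 1993. The stem set was 647 from the series matrix and 1800 with the percentile over all probes. With 1 transcript per locus (19482 tested) the counts were 2526 for stem and 1359 for root against whole plant, 4661 for leaf versus root, 7098 for leaf versus stem, 5499 for stem versus root, and 1032, 1958 and 954 for the leaf, stem and root sets, with 28 of the 114 list tests still run passing, in place of 43 of 120, and 78 of the 82 named comparisons. With only specific probes (18034 tested) they were 1277, 1955 and 1267 for leaf, stem and root against whole plant, 4055, 6033 and 4643 for leaf versus root, leaf versus stem and stem versus root, 874, 1519 and 842 for the leaf, stem and root sets, 22 of 120 list tests and 66 of the 69 named comparisons.

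The replicate number equals the slide. Across transcripts, deviations of replicates with the same number correlated at 0.185 to 0.258 in 5 of 6 pairs of groups and at 0.0388 for stem and whole plant. Pairing was neither established for all groups nor excluded. With the replicate block, stem versus whole plant gave 8763 in place of 5317, of which 5315 were shared, and 42 of the 43 list calls at the preset correlation held. No other count moved by over 1.5 times with the block.

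Leaving out 1 array assumes that the lone sample of its group varies like the others. The ranges were 558 to 2357 for leaf, 159 to 3927 for stem and 760 to 2988 for root against whole plant, 4792 to 9171 for leaf versus root, 5859 to 12992 for leaf versus stem, 2953 to 9530 for stem versus root, 1040 to 2028 for the leaf set, 739 to 3227 for the stem set and 676 to 1338 for the root set. The list calls ranged from 42 to 46 and the named transcripts from 91 to 110. Without leaf replicate 1 leaf versus whole plant gave 1023, leaf versus root 4820, leaf versus stem 5859, the leaf set 1040 and the stem set 1604. Without leaf replicate 2 they were 1040, 5552, 9422 and 1441 for the first 3 comparisons and the leaf set. Without root replicate 1 root versus whole plant gave 1175, stem versus whole plant 2563, leaf versus root 5040, stem versus root 2953, the stem set 739 and the root set 678. Without root replicate 2 they were 845, 2563, 4792, 4338, 1509 and 676, and the leaf set 1505. Without stem replicate 2 stem versus whole plant gave 1707, stem versus root 6995 and the stem set 1732. Without whole plant replicate 1 leaf, stem and root against whole plant gave 558, 159 and 1255, and without replicate 2 they gave 1140, 339 and 760.

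Of the named transcripts that passed, 5 changed direction. After normexp, stem minus whole plant was 0.57 for locus 9555 and 0.62 for locus 11121, and stem minus root was 1.35 for SWEET2. With no filter on dim probes root minus whole plant was 0.88 for zeaxanthin epoxidase, and with probes well above background on all arrays leaf minus stem was -0.78 for catalase, through its other probe.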

Other observations

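The sets in the first paragraph and the tests of the floor, the scaling and the scan pass in the last were chosen only after the results were seen, and the quantile normalization test before. The 3 comparisons with whole plant share its arrays, and no count without change was simulated for them. In whole plant, 13 transcripts of 9 loci were higher than in leaf, stem and root alike by limma, and 4 were lower than in all 3. Those with a protein name were an alpha/beta-hydrolase of locus 5604, at 0.12 in whole plant against -5.40 in leaf, -2.67 in stem and -2.83 in root, and Kirola, a protein named after a kiwifruit allergen, at 1.83 against -0.04, -0.31 and -5.00. With a common floor for dim signals the count was 19. Of the 8397 transcripts that differed between leaf and root, 7042 (83.9%) had a whole plant mean between those of leaf and root. They were selected for a gap between leaf and root, which by itself favours a high share. No share for comparison was computed, so no conclusion is drawn from it.

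The 3 transcripts of the microbe list, whose annotation names hypothetical proteins of Streptomyces, were well above background on every array, except that of locus 13599, which was on neither stem array. The transcript of locus 7465 was at 2.55 in root, 1.5 in whole plant, -0.25 in stem and -4.39 in leaf, that of locus 8878 at 1.82, 0.95, 0.86 and -2.78, and that of locus 13599 at -3.19, -4.20 and -3.55 in root, whole plant and leaf. For leaf versus root the adjusted p was 0.000243, 0.00921 and 0.643. What organism they belong to was not tested.

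More transcripts were higher in stem than in both other organs (3873) than in leaf (2282) or root (1432). For a higher floor of dim signals on the stem arrays, the counts with a common floor were 3809, 2342 and 1365. That floor leaves almost unchanged the stem values of the 3648 members well above background on both stem arrays. It also gives dim arrays equal values without spread. The stem count could therefore hardly fall, and the test does not decide on the floor. A different distribution of signals on the stem arrays cannot be told apart from a difference between organs, since after quantile normalization the counts were 2634, 2599 and 1674, neither below the leaf count nor over 1.1 times it. The scaling of the stem arrays cannot be told apart from a difference between organs either, by a rule that was written, and then made stricter, with the counts known. The signals of spike-in controls were not used in that rule, and no fit was scaled to them. Every spike-in probe was brighter on both stem arrays than on the 6 other arrays. Probe E1A_r60_a20 had a median log2 signal of 10.03 and 10.55 on the stem arrays and 7.23 to 8.74 on the others. The 75th percentile of processed signal over all probes was 19.6 and 25.5 on the stem arrays and 36.6 to 63.7 on the others. Relative to the spike-ins, that percentile thus lay lower on the stem arrays. The stem count was 647 from the median-centred series matrix and 1800 with the percentile over all probes, both under the leaf count, but 18962 after normexp. The percentile over all probes moves all values of an array by one constant, so a fall in the stem set is built into its downward shift. The series matrix differs both in its centring and in its floor of 1 on the 6 other arrays, and normexp is a background correction, so neither isolates the scaling. The separate scan pass and detector voltage of the stem arrays, whose lowest well-above-background signal lay 2.20 log2 units above the others, cannot be told apart from stem, because no pass held stem and another group. A difference between the organs themselves stays open and untested.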
